A study of Mus musculus with 6 samples.

How the data were processed

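RNA came from MN9D cells, a mouse dopaminergic cell line, transfected with a plasmid carrying the Lmx1a coding sequence or with the empty plasmid. Per the labels, 3 pools of RNA from Lmx1a-transfected cells, each from 3 dishes, were hybridised on 2-colour arrays against 1 pool of RNA from 9 dishes of control cells. Each pool was run with Lmx1a RNA in Cy5 and again with Lmx1a RNA in Cy3, giving 6 arrays. The arrays of 1 pool share the same 2 RNA extracts and were counted as 1 replicate, so n = 3. The control pool is 1 sample and the ratio was tested against 0, which leaves out the spread between control cultures. The labels do not say whether the 3 pools came from separate transfections, so p-values measure the spread between these pools only.

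The deposited scanner tables hold the intensity of each spot on a linear scale, as the mean of the spot pixels and the median and standard deviation of the surrounding background, per the file headers. The scanner, its software and its version are not given in the sources used here. The authors also deposited a table of log2 ratios. Set against the scanner values, these were log2 ratios of Lmx1a over control on every array, with swapped arrays already turned and values centred within each of 48 print grids. They followed a loess fit of mean spot intensity within print grids without background subtraction, with a correlation across spots of 0.996 to 0.999 and a slope of 1.00 on each array. Column medians were 0.0037, 0.0042 and 0.0040 for replicates 1, 2 and 3 with Lmx1a in Cy5, and -0.0014, -0.0028 and -0.0034 with Lmx1a in Cy3. Scale and centring were read from the values, since no label states them. The sample titles name the 2 RNAs in dye order, so for swapped arrays they run opposite to the direction the values showed. This table served as an alternative only.

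Each array held 34992 spots. The 3223 control spots, recognised by their identifiers, entered the background model, had weight 0 in the loess fit and were then left out, leaving 31769 probes. Of these, 26000 had 1 gene name, 0 had several and 5769 had none. Names came from GEO's platform annotation. RefSeq's gene table for assembly GRCm38.p6 was used for names only: 23070 were current, 2865 were updated through a synonym and 65 were kept as given. The probes named 17865 genes.

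Background was corrected with normexp and an offset of 50, and log2 ratios were normalized within each array by loess with a span of 0.3. Ratios were turned to read Lmx1a over control, and the 2 arrays of each pool were averaged. The mean of the 3 replicates was tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. Dye bias was tested in the same way on Cy5 over Cy3. A spot was taken as detected where its mean exceeded the background median by 2 background standard deviations. The number of arrays limits the precision.

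Before the data were examined, 30 gene lists with 816 genes were fixed, of which 761 genes were measured. They were tested with limma's camera at a preset correlation of 0.01 on the brightest probe of each gene, and again with an estimated correlation and with fry. The genes named in the text followed a rule also fixed then. It takes Lmx1a, Rgs4 and Grb10. It takes the 10 genes with the largest change in each direction among those past the threshold, with 1 sign on all 6 arrays and above-median brightness, or, if none pass, the 10 with the smallest p on each side. The filters on sign and brightness were kept in this second case. From each list it takes up to 4 members past the threshold or, if none pass, the 2 with the smallest p. Genes outside the rule are said to have been chosen after their values were seen.

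The procedure was tested on simulated data built on the 31769 probes, with the spread of each probe drawn from the fitted prior. In all, 200 probes were changed, 50 each by 1.1, 1.2, 1.5 and 2-fold. At adjusted p under 0.05 the limma fit recovered 40.0% of 1.1-fold changes, 90.0% of 1.2-fold changes and 100% of 1.5-fold changes, with 12 false calls among 177. The fit of 6 arrays with a replicate block recovered 72.0%, 96.0% and 100%, with 8 false calls among 192. Large changes ease the Benjamini-Hochberg cutoff for small ones, and the real arrays held only 2 probes of at least 1.5-fold. These shares therefore need not hold for the real data. In a set of 30 simulated genes camera gave a p of 3.61e-13 with a shift of 0.05 and 0.773 without. These genes were simulated without correlation between them. In the real data the estimated correlation was 0.484 for the hypoxia and glycolysis list and 0.449 for the cell cycle and DNA replication list. The simulation therefore does not test camera's preset correlation on such lists. The simulation gave the 2 arrays of a pool independent errors.

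The alternatives were no background correction, plain subtraction, loess within print grids, median centring, Aquantile scaling, the authors' values, only detected probes, other probes of a gene or their mean, each dye orientation alone, each replicate left out, a variance trend with a robust prior, a minimum fold, and all 6 arrays with a dye term and the replicate as a block through duplicateCorrelation. The replicate number names the RNA pool, so the block joins the 2 arrays of a pool. The fit without the dimmest array was added after the data were seen. Spot flags, slides, scan and print batches are not given in the files used here, so these alternatives were not run.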

Results

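The arrays compared gene expression in MN9D cells overexpressing Lmx1a, a LIM homeodomain transcription factor of midbrain dopaminergic development, with expression in cells given the empty plasmid. The series names Rgs4 and Grb10 as genes activated by Lmx1a. There were 3 Lmx1a RNA pools, each measured on 2 dye-swapped arrays against the same control pool. Median background-subtracted brightness per array ranged from 12.9 to 42.4 units in Cy5 and from 9.02 to 20.7 in Cy3. The array of replicate 1 with Lmx1a RNA in Cy3 was the dimmest, with 49.2% of probes detected in the Lmx1a channel, against 60.1% to 67.7% on the other 5. In all, 14256 probes (44.9%) were detected in at least 1 channel on every array.

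The first question was how the signal of the transfected gene differed. The Lmx1a log2 ratio was 2.49 ± 0.68 (SD, n = 3), or 5.61-fold, and was positive on 6 of 6 arrays. The replicates gave 1.71, 2.78 and 2.97. Its limma adjusted p was 0.0779, above the threshold. With the 6 arrays fitted with a replicate block, limma's adjusted p was 0.0121, and without replicate 1 the log2 ratio was 2.88 with an adjusted p of 0.00117. The dimmest array gave 0.93, and the other 5 gave 2.5 to 3.19. Background subtraction without an offset gave a mean log2 ratio of 3.79, with an adjusted p of 0.335. The control channel of the Lmx1a probe was above background on 5 of 6 arrays. Whether the probe lies within the sequence carried by the plasmid was not checked here, so the value does not separate plasmid from endogenous transcript.

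Rgs4, a regulator of G protein signalling, had a log2 ratio of 0.16 ± 0.052 (SD, n = 3), positive on 6 of 6 arrays, with a limma adjusted p of 0.106. Grb10, an imprinted gene encoding an adaptor of insulin and IGF receptors, had a log2 ratio of 0.10 ± 0.041 (SD, n = 3), positive on 6 of 6 arrays, with a limma adjusted p of 0.166. In folds, Rgs4 was at 1.12 and Grb10 at 1.07. Neither passed the threshold. In the replicate block fit the adjusted p was 0.0189 for Rgs4 and 0.0499 for Grb10. Without the dimmest array, an alternative chosen after the data were seen, these became 0.0537 and 0.079. On the arrays with Lmx1a in Cy3 alone Rgs4 was at 0.094 (adjusted p 0.203), and plain background subtraction gave 0.31 for Rgs4 and 0.20 for Grb10 (adjusted p 0.733 for each). A pair of further Grb10 probes was not well above background on any array. Since the study names both genes, possibly from these arrays, their direction here is not independent evidence.

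**Figure D1:**
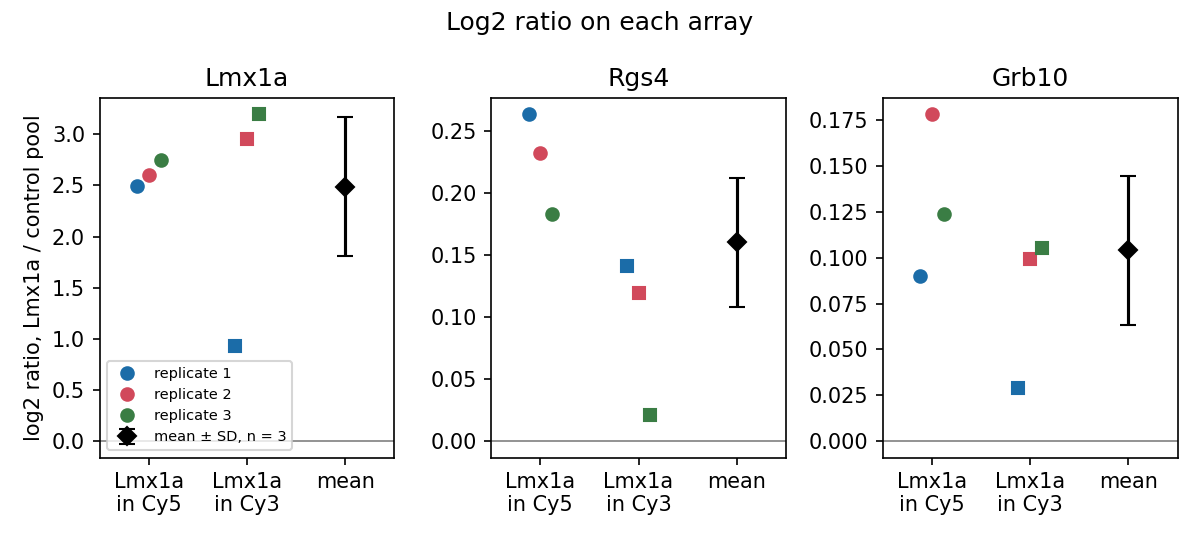
Log2 ratio of Lmx1a-transfected cells over the control pool for Lmx1a, Rgs4 and Grb10 on each of the 6 arrays (vertical axis, 1 scale per gene), by the dye that carried the Lmx1a RNA, with circles for Cy5, squares for Cy3, 1 colour per replicate, and the mean ± SD of the 3 replicates as a diamond with a bar. All values lie above 0, and the Lmx1a value of 0.93 on the dimmest array lies below the other 5, at 2.5 to 3.19.

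Of all probes, 2 had ratios of at least 1.5-fold in either direction, whatever their p. These were Lmx1a and Erbb2, a receptor tyrosine kinase gene named after its value was seen, at -0.83 ± 1.45, where 1 array gave -5.05 and the other 5 gave -0.041 to 0.050. Apart from Lmx1a, the probes called in the replicate block fit had log2 ratios between -0.29 and 0.24, and the median size over all of them, Lmx1a included, was 0.15. In limma's fit of the 3 replicates 0 of 31769 probes passed an adjusted p of 0.05. The smallest adjusted p was 0.0779, shared by 60 probes. Without replicate 1 the count was 1, Lmx1a itself, and with median centring in place of loess it was 49, 6 higher and 43 lower. At an unadjusted p under 0.05 there were 3743 probes, 1978 higher and 1765 lower, where p-values spread evenly from 0 to 1 would give 1588. That figure leaves out the control pool that all arrays share. The replicate block fit called 333 probes, 95 higher and 238 lower, and without the dimmest array 91, of which 79 were among the 333. That fit counts the 2 arrays of a pool as nearly independent, with a consensus correlation of 0.0684.

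Since no gene passed the threshold, the 10 genes with the smallest p in each direction are given as values. They were taken from genes with 1 sign on all 6 arrays and above-median brightness, so their agreement in sign follows from the choice. Choice by p also favours a small SD between pools, which leaves out the spread between the arrays of a pool. Among the genes with positive ratios, Slc18a2, the vesicular monoamine transporter, had a log2 ratio of 0.20 ± 0.053 (limma adjusted p 0.0799). Itch, a ubiquitin ligase, was at 0.20 ± 0.038 and Bpnt1, a nucleotidase, at 0.19 ± 0.020. The small GTPase gene Rap1b was at 0.17 ± 0.015 (0.031 to 0.296 on single arrays) and the Ran-binding protein gene Ranbp1 at 0.16 ± 0.026. H3f3b, encoding histone H3.3, was at 0.14 ± 0.030, Vapa at 0.13 ± 0.020, Gclc, of glutathione synthesis, at 0.13 ± 0.021, and the olfactory receptor gene Olfr132 at 0.12 ± 0.0047. A second probe gave 0.051 for Bpnt1, positive on 4 of 6 arrays, 0.047 for Gclc, on 6 of 6, 0.10 for H3f3b, on 5 of 6, and -0.0066 for Olfr132. Some of these ratios sat mostly in 1 dye orientation. Itch was at 0.045 with Lmx1a in Cy5 (limma adjusted p 0.449) and 0.35 in Cy3, and Olfr132 at 0.21 in Cy5 and 0.023 in Cy3 (adjusted p 0.628). Ranbp1 (0.096) and Vapa (0.068) were lower with Lmx1a in Cy5 and Slc18a2 (0.13) in Cy3, while median centring gave 0.067 for Ranbp1 and 0.038 for H3f3b. Plain subtraction gave 0.34 for Itch and median centring 0.20 for Olfr132. In the replicate block fit the adjusted p was 0.0121 for Slc18a2, 0.0189 for Itch and 0.0175 for Ranbp1, while Rap1b (0.0642) and H3f3b (0.069) did not pass.

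Among these 10 genes with negative ratios, 4 encode cytosolic ribosomal proteins. Rpl38 was at -0.26 ± 0.036, Rps28 at -0.25 ± 0.046, Rpl31 at -0.23 ± 0.016 and Rps29 at -0.23 ± 0.030 (SD, n = 3). Their limma adjusted p was 0.0779. The 4 other probes of Rpl38 gave -0.16 to -0.29 and other probes gave -0.20 and -0.23 for Rpl31 and -0.15 and -0.25 for Rps29. The ribosomal pseudogene Rpl30-ps5 was at -0.15 ± 0.0032 (-0.039 to -0.249 on single arrays), and sequences of such copies can cross-hybridise with their parent genes. The ATP synthase gene Atp5mpl was at -0.22 ± 0.048, and the complex I genes Ndufb2 at -0.17 ± 0.030 and Ndufa2 at -0.16 ± 0.011. Olfr43 was at -0.19 ± 0.044 (-0.11 with Lmx1a in Cy5) and Trp53i13 at -0.14 ± 0.0021. All 10 passed in the replicate block fit, with adjusted p from 0.00353 for Rpl31 and Rpl38 to 0.0324 for Ndufb2.

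**Figure D2:**
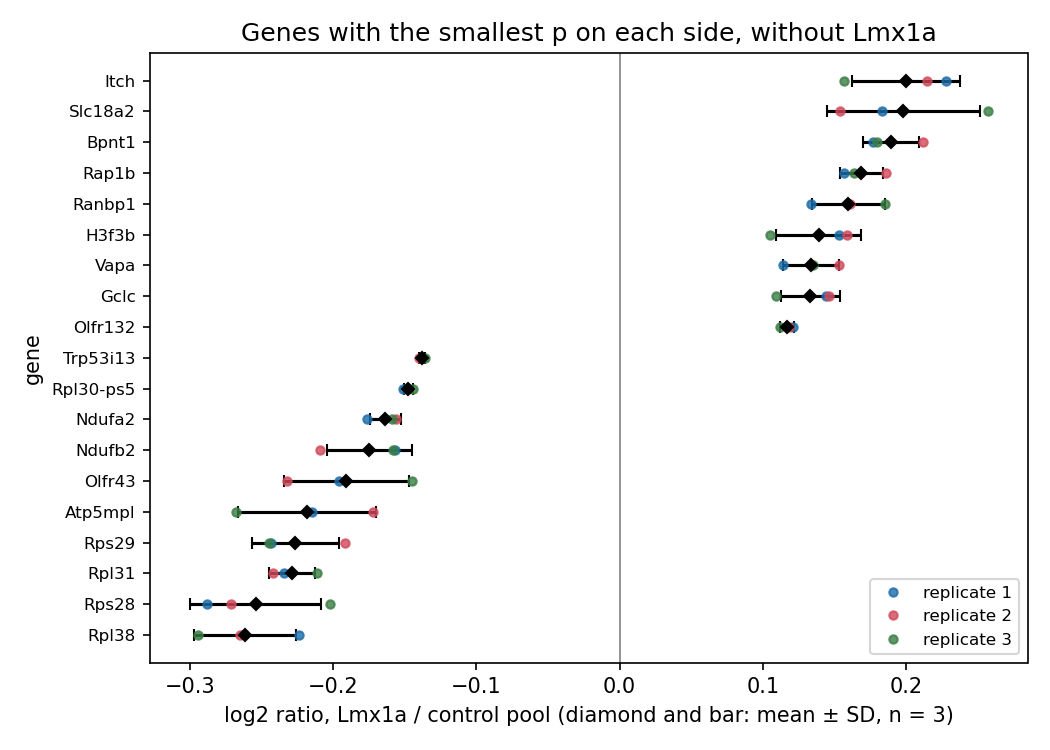
Log2 ratio of Lmx1a-transfected cells over the control pool (horizontal axis) for the 19 genes other than Lmx1a with the smallest p on each side (vertical axis), with circles for the 3 replicates and a diamond with a bar for the mean ± SD. Slc18a2 and Itch lie at 0.20 and Rpl38 at -0.26. The genes were chosen among those with 1 sign on all 6 arrays, so each gene's 3 replicates lie on 1 side of 0 by the choice.

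Genes of dopamine synthesis, storage, transport and breakdown went both ways, with 9 of 14 measured members above 0 and a median log2 ratio of 0.012. Adjusted over the list alone, 3 passed in limma's fit. These were Slc18a2 (0.20, positive on 6 of 6 arrays), Ddc (0.085, on 5 of 6), encoding aromatic amino acid decarboxylase and named after its value was seen, and Gch1 (-0.094, negative on 4 of 6), the first enzyme of tetrahydrobiopterin synthesis. The Gch1 ratio sat in 1 dye orientation, at -0.19 with Lmx1a in Cy5 and -0.00040 in Cy3 (adjusted p over the list 0.988). Of all 12 genes that passed over a list alone, Slc18a2 alone also passed with the same sign in each dye orientation by itself, and 0 passed with plain subtraction or with the variance trend and robust prior. Over all probes 0 of the 14 passed in limma's fit, with 4 higher and 1 lower at an unadjusted p under 0.05, and in the replicate block fit Slc18a2 alone did, while over the list alone that fit called 4 higher and 1 lower. Th, encoding tyrosine hydroxylase and chosen after its values were seen, had a log2 ratio of 0.0067 ± 0.16, with 0.11, -0.18 and 0.091 in the 3 replicates. The developmental transcription factors of these neurons had a median of 0.0054 over 22 genes, with Tcf12 at 0.098 ± 0.052 and Nr4a1 at -0.047 ± 0.046, and the subset genes a median of 0.011 over 26, with Slc17a6 at 0.12 ± 0.12 and Vip at 0.068 ± 0.033. Slc17a6 was at 0.053 without replicate 2, and with Lmx1a in Cy5 it was at 0.051 and Nr4a1 at -0.0084. Nr4a1 gave 0.007, -0.076 and -0.071 in replicates 1, 2 and 3. Tcf12 was at 0.055 with Lmx1a in Cy3, and median centring gave 0.15 for Tcf12, -0.022 for Nr4a1 and 0.030 for Vip, for which plain subtraction gave 0.27. RGS and heterotrimeric G protein genes had a median of 0.0073 over 36, and Gnb4 (0.10, with 0.048 in Cy5 and 0.16 in Cy3) passed over the list alone. Rgs4 was not a member of that list, nor Lmx1a of the developmental transcription factor list. Grb10 was not in the imprinted or the insulin and IGF list. These 3 genes were therefore not tested over those lists.

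Camera of limma called 3 of the 30 lists at its preset correlation, all with positive medians. None of the 3 calls held with an estimated correlation (adjusted p = 0.961 for each), and fry called 0 lists (smallest adjusted p 0.181). Of the hypoxia and glycolysis genes, 31 of 32 had positive ratios, with a median of 0.069 that was positive on 6 of 6 arrays (adjusted p 2.27e-06). Cell cycle and DNA replication genes had 36 of 45 above 0 and a median of 0.053, positive on 5 of 6 arrays (adjusted p 2.27e-06), with Rrm2, a ribonucleotide reductase subunit, at 0.14 ± 0.093 (0.089 without replicate 2) and Mcm6, of the replicative helicase, at 0.11 ± 0.048. The unfolded protein and amino acid stress list had 20 of 30 above 0 and a median of 0.035, positive on 5 of 6 arrays (adjusted p 0.00366). Its members Pdia6, a protein disulfide isomerase (0.11), and Psat1, of serine synthesis (0.10), passed when adjusted over the list alone, where 2 of the 30 and 0 members of the hypoxia and cell cycle lists did. They did not pass there on the arrays with Lmx1a in Cy3 (0.037 and 0.042) or with median centring (0.097 and 0.029), and other Pdia6 probes gave 0.12 and 0.022. In limma's fit over all probes, 0 members of these lists passed, with 8, 14 and 13 at an unadjusted p under 0.05, all higher, and in the replicate block fit Pdia6 alone passed (adjusted p 0.0257). Adjusted over the list alone, the replicate block fit called 9 members of the unfolded protein list, all higher, and 0 of the other 2 lists.

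The replicates differed in these lists. Replicate medians of the hypoxia and glycolysis list were 0.22, 0.028 and 0.015, and without replicate 1 its median was 0.022 with a camera adjusted p of 0.131, against 0.118 without replicate 2. Its members Mxi1 and P4ha1 had log2 ratios of 0.14 ± 0.084 and 0.15 ± 0.11. Without replicate 1 P4ha1 was at 0.093, with Lmx1a in Cy5 at 0.066 and in Cy3 at 0.24, plain subtraction gave 0.28, and its other detected probe gave 0.013. Adm, encoding adrenomedullin, and Bnip3, a mitophagy receptor, chosen after their values were seen, had 0.95, 0.31 and 0.066, and 0.67, 0.13 and 0.070, in replicates 1, 2 and 3. The cell cycle list had replicate medians of 0.041, 0.14 and 0.0091, at percentiles 99.93, 100 and 75.85 of 10000 random lists matched on brightness, and without replicate 2 its median was 0.023 with an adjusted p of 0.0612. The unfolded protein list gave 0.021, 0.039 and 0.046, and its median was 0.032 without replicate 3 (adjusted p 0.0973) and 0.057 without replicate 1. This call was also lost with plain background subtraction (adjusted p 0.132), with median centring (0.066) and on the arrays with Lmx1a in Cy3 (0.721).

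**Figure D3:**
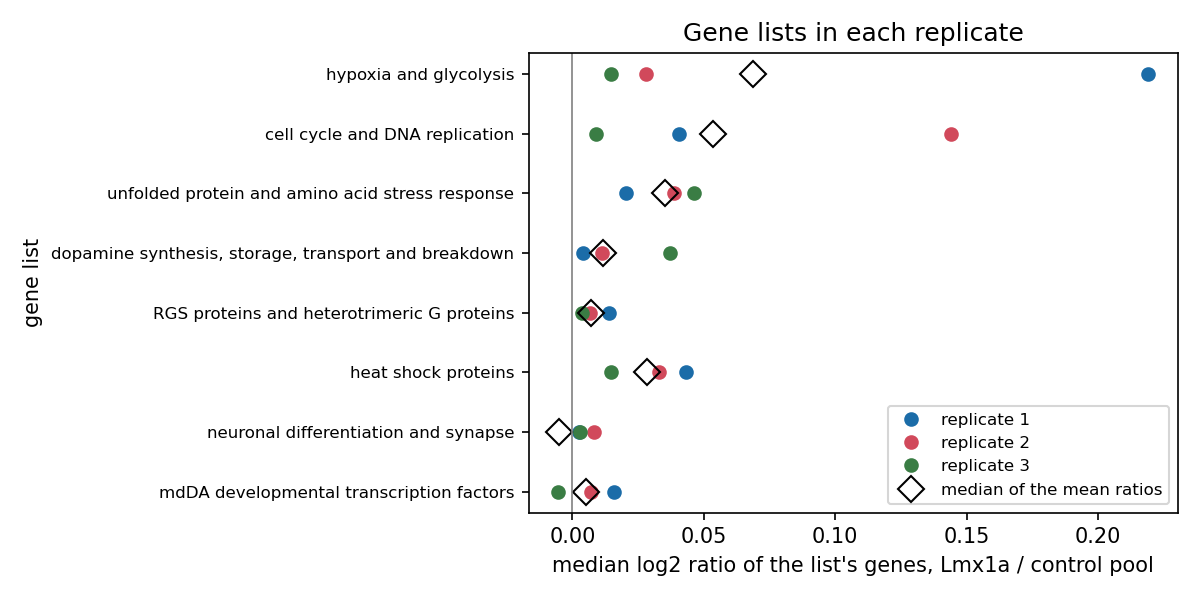
Median log2 ratio of the genes of 8 lists, Lmx1a-transfected cells over the control pool (horizontal axis), with circles for the 3 replicates and an open diamond for the median of the mean ratios. Replicate 1 lies at 0.22 for hypoxia and glycolysis and replicate 2 at 0.14 for cell cycle and DNA replication, away from the other replicates of the same list.

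The other 27 lists were not called by camera (adjusted p from 0.0927 to 0.959), though without replicate 1 the reference genes were (adjusted p 0.00842, median 0.043). Heat shock genes had a median of 0.029, and adjusted over the list alone Dnaja1 (0.11) and Hspe1 (-0.13), a mitochondrial co-chaperonin, passed, each with its sign on 5 of 6 arrays. Dnaja1 was at 0.023 with Lmx1a in Cy5, and its other probes gave 0.051 and 0.060, while Hspe1 was at -0.0087 in Cy3. A second Hspe1 probe gave -0.19, negative on 6 of 6 arrays and so in both orientations. Hspa8 (0.070), named after its value was seen, also passed there, but was positive on only 3 of 6 arrays, with -0.11 in Cy5 and 0.25 in Cy3. With median centring Hspa8 was at -0.061. TGF-beta and BMP genes had a median of 0.022, reference genes 0.024, with Gapdh at 0.19 ± 0.15 and Eef1a1 at 0.13 ± 0.091, and noradrenergic and neuroblastoma markers 0.021, where the granin gene Chgb (0.22, positive on 6 of 6 arrays) passed over the list alone. Gapdh was at 0.11 without replicate 1 and 0.074 with median centring, and its other probes gave 0.063, 0.11 and 0.22. Eef1a1 was at 0.23 with Lmx1a in Cy5, 0.031 in Cy3 and -0.0040 with median centring. Chgb did not pass over its list with loess within print grids (0.14, adjusted p over the list 0.196), the authors' values (0.14) or median centring (0.11), and was at 0.095 with Lmx1a in Cy5 and 0.34 in Cy3. Over their lists alone, the immediate early gene Egr1 (0.13) and the imprinted gene Peg3 (0.12) also passed, in lists with medians of -0.00033 and -0.0028, and both passed in the replicate block fit (adjusted p 0.0202, positive on 6 of 6 arrays, and 0.0447, on 5 of 6). Median centring gave 0.20 for each and plain subtraction 0.24 and 0.25, and Peg3 was at 0.047 with Lmx1a in Cy5. Signalling lists had medians of 0.0012 for Wnt, -0.00032 for Notch, -0.00062 for Shh and floor plate, and 0.0039 for insulin and IGF. Neuronal differentiation and synapse genes had a median of -0.0051, axon guidance genes 0.0064, channels -0.0021 and neural progenitor markers -0.00084. Apoptosis genes were at 0.0081, cell cycle inhibitors and p53 targets at 0.0059, interferon response genes at -0.0011 and cholesterol genes at -0.0027. Among markers of other cell types, medians were -0.0090 for astrocytes, 0.0029 for oligodendrocytes, 0.0022 for microglia and leukocytes, -0.0021 for fibroblasts and smooth muscle, and 0.0038 for other neurons. The median was negative but the mean positive for the immediate early, imprinted, interferon, cholesterol, Notch, neural progenitor and neuronal differentiation lists, and the reverse for oligodendrocyte markers. Camera's direction followed the mean in these lists, except that it was down for the imprinted and cholesterol lists, and it was down for microglia and leukocyte markers, whose median and mean were positive. Olig1 and Ntn1 were not well above background on any array.

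At an adjusted p under 0.05 in limma's fit, 2160 probes were dye-biased, 843 brighter in Cy5 and 1317 in Cy3. The count depended on the processing, with 4261 without background correction, 24782 with median centring, 1 with plain subtraction and 0 with the variance trend and robust prior. It was 722 without replicate 2 and 503 without replicate 3. Across probes, which are not independent replicates, arrays of different pools with the same dye orientation correlated at 0.32 to 0.50, and the 2 arrays of 1 pool at -0.21 to 0.032. Averaged over the swap, the replicates correlated at 0.25 to 0.38, and since all share 1 control pool, part of this correlation would be present with no effect of Lmx1a. The ratio had 1 sign on all 6 arrays for 1676 probes (5.28%), where independent signs would give 3.125%. That figure leaves out the shared control pool and dye bias. The mean ratio differed in sign between the 2 orientations for 19678 probes (61.9%).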

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

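The tests of the dim Lmx1a spot and of weak labelling were chosen after the result was seen. Of 109 genes and list medians examined over the 6 arrays, 6 had 1 array set apart from the other 5 by a gap that takes up most of the whole range, past Dixon's critical value, and chance gives about 1 in 20. The Lmx1a log2 ratio was 0.928 on the array of replicate 1 with Lmx1a RNA in Cy3, and 2.5 to 3.19 on the other 5. That array was also dim as a whole, with 49.2% of probes detected in the Lmx1a channel against 60.1% to 67.7% on the other 5. With plain background subtraction the Lmx1a value was 3.36, 0.515 log2 units below the mean of the other 5. The control channel of this spot was not above background on that array, so the value of 3.36 is uncertain. The fixed offset of 50 on a dim spot may contribute to the low ratio. The authors' values, which followed a fit without background subtraction or this offset, gave 0.936 on that array. A low ratio thus also appeared without the offset. In the Lmx1a channel the spot was at 40.5 units, against 424 and 548 on the other arrays with Lmx1a in Cy3. Median brightness in that channel was 9.02 on this array and 20 and 20.4 on those. Weak labelling of the whole array may thus account for only part of the dimness, and a cause particular to this spot was not tested. No biological explanation was tested, since the same RNA pool gave 2.5 with the dyes swapped.

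Ier3 was at 0.262 on the array of replicate 1 with Lmx1a in Cy5, with 0.042 to 0.117 on the others. Slc17a6 was at 0.396 on the array of replicate 2 with Lmx1a in Cy3, with -0.00077 to 0.132 on the others. Itgam was at 0.019 on the array of replicate 1 with Lmx1a in Cy5, with 0.0439 to 0.0517 on the others. Vim was at 0.257 on the array of replicate 2 with Lmx1a in Cy5, with 0.0612 to 0.118 on the others. The median of the developmental transcription factors was -0.0197 on the array of replicate 2 with Lmx1a in Cy3, with 0.0018 to 0.012 on the others.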

How the results depend on the processing

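The fit without the dimmest array was chosen after the data were seen, and the cause of the changes below was not tested unless stated. No background correction, loess within print grids, Aquantile scaling, which leaves the ratios as they are, the authors' values and the restriction to detected probes all kept 0 changed probes, the 3 lists and the direction of each named gene they tested. The mean of all probes of a gene also kept the 3 lists. Plain subtraction, treat against 1.2-fold, the 1.5-fold minimum and the variance trend also gave 0 probes. Changed probes numbered 49 with median centring (6 higher, 43 lower), 333 with the dye term and replicate block (95 higher, 238 lower), 993 from the arrays with Lmx1a in Cy5 (340 higher, 653 lower), 215 from those with Lmx1a in Cy3 (133 higher, 82 lower) and 91 without the dimmest array (13 higher, 78 lower). In a single orientation dye bias is not cancelled. Leaving out a replicate gave 0 to 1, the 1 being Lmx1a without replicate 1. Lmx1a passed with median centring (2.58), the replicate block (2.49), Cy5 alone (2.62) and without the dimmest array (2.84), and ranged from 2.25 to 2.88 with a replicate left out. Rgs4 passed with the replicate block (0.16) and in Cy5 alone (0.23), and Grb10 with the replicate block (0.10). Rgs4 was at 0.094 in Cy3 alone, and plain subtraction gave 0.31 for Rgs4 and 0.20 for Grb10. Limma's adjusted p over all alternatives ran up to 0.733 for Rgs4 and Grb10. Dye-biased probes numbered 4261 with no background correction, 1 with plain subtraction, 24782 with median centring, 0 with the variance trend and 503 to 1514 with a replicate left out. With an estimated correlation 0 lists passed, at unchanged medians of 0.069, 0.053 and 0.035, and fry called 0. The unfolded protein list was lost with plain subtraction (0.055), median centring (0.029) and Cy3 alone (0.020). With a replicate left out, medians ran from 0.022 to 0.118 for hypoxia, 0.023 to 0.077 for cell cycle and 0.032 to 0.057 for unfolded protein, each losing its call once, and reference genes were called without replicate 1 (0.043). The replicate block kept the 3 lists. Calls over a list alone were set against 14 of the alternatives after the data were seen. Aquantile scaling was among these alternatives and leaves the ratios as they are, so each gene passed there by construction. Slc18a2 passed in 12, Gch1 and Egr1 in 9, Pdia6 in 8, Ddc in 7, and Gnb4, Hspe1, Peg3, Chgb and Psat1 in 6. Dnaja1 and Hspa8 passed in 4, Hspa8 once with the opposite sign. None passed with the variance trend or plain subtraction. Of 76 other named genes 20 passed with the block. Signs turned with median centring for Rfng (-0.014), Col1a2 (0.021), Eef1a1 (-0.0040) and, not among the 76, Hspa8 (-0.061). They turned in Cy5 alone for Hes1 (-0.016), Smad1 (-0.0087), Idi1 (-0.049) and Hspa8 (-0.109). They turned in Cy3 alone for Gna12 (0.163), Gjb6 (-0.015), Apoe (0.016), Ephb2 (-0.148), Igfbp6 (-0.032), Tsc2 (0.028) and Ina (-0.012). Other probes had the opposite sign for Olfr132 (-0.0066), Ephb2 (-0.00040 and -0.033), Sema6a (-0.0098), Pmvk (0.024), Idi1 (-0.0048), Col5a1 (-0.031, -0.0047 and -0.042) and Slc22a18 (0.011). Another 9 probes of named genes were not above background on any array and were left out of this comparison, some with the opposite sign. Dim signal limits the ratios, since the offset draws those of dim spots toward 0. Spot flags and slide, scan or print batches were not run.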

Other observations

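The tests on small mRNAs, on the control pool and on differences between the Lmx1a pools, and the gene families in this part, were chosen after the results were seen. Genes of the cytosolic ribosome and the respiratory chain lay below 0 as groups. Of 66 ribosomal protein genes, 60 had negative ratios, with a median log2 ratio of -0.067 and 13 called lower in the replicate block fit. Of 83 genes taken as respiratory chain by name prefix, ATP synthase genes included, 67 had negative ratios, with a median of -0.071 and 15 called lower. The prefixes also match names of complex I assembly factors. Both medians were negative on 6 of 6 arrays and under each normalization, from -0.062 to -0.14 for ribosomal and -0.064 to -0.11 for respiratory chain genes. As for all other probes, none of them passed an adjusted p of 0.05 in limma's fit of the 3 replicates.

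Several explanations were weighed for these families. Among 10000 random lists matched on brightness, 0% had a median as low as that of both families together. Loess centres the ratios at each brightness, so such lists lie near 0 by construction. The draws therefore do not decide on brightness-dependent normalization as the cause. With median centring in place of loess, the median of both families together was -0.12, against -0.068 with loess. Other families of small proteins, 83 genes such as those of Lsm proteins and prefoldin, were also low, with a median of -0.035 at percentile 0. A lower yield of small mRNAs as a class may therefore contribute. Protein family stood in for mRNA size here, since transcript lengths were not used, so this was not tested directly. Some of these families hold members called lower in the replicate block fit. The 52 genes of families with no called member known had a median of -0.013, at percentile 0.47, and in replicate 3 at percentile 23.52. The highest replicate median of both families together was -0.055, and since every array shares 1 control pool, an effect of Lmx1a and a feature of that pool cannot be told apart.

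The hypoxia and glycolysis list was high mainly in 1 replicate. Its median was above that of 100% of random lists matched on brightness. Such lists lie near 0 by construction, so this does not decide on brightness-dependent normalization. The draws also leave out the correlation between the list's genes, estimated at 0.484. With median centring in place of loess the list's median was 0.076. Taken per replicate, the list's median lay above the range of these random lists in 1 of 3 replicates, with percentiles of 100, 95.56 and 89.37. Differences between the Lmx1a pools unrelated to the plasmid they share, such as culture density, are a candidate explanation. An effect of Lmx1a of unequal size between pools stays open, as no pool of control cells was measured by itself.

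Turning the sign of 1 replicate gives 4 sign patterns, too few for a share under 0.05. For the 333 probes of the replicate block fit, 1 of the 4 patterns, the real one, gave as many, and the highest other gave 0. For the 3 gene lists, 1 of the 4 gave as many, and the highest other gave 2. Since all replicates share 1 control pool, their ratios lean to the same sign even with no effect of Lmx1a. The real pattern was therefore favoured in advance, and no conclusion is drawn from these counts.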
